A study of Homo sapiens and Mus musculus with 13 samples.

How the data were processed

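The series comprises 13 samples. The 9 peak lists analysed here cover DRIP-seq and DRIPc-seq, 6 lists from human and 3 from mouse cell lines, and samples were grouped by cell line, assay, restriction digest and RNase treatment, per the labels. NT2 DRIPc-seq has 2 samples and 1 peak list, which the labels name for both, so the samples were combined by the authors in a way that is not given in the sources used here. The other 8 lists belong to 1 sample each. The 2 NT2 RNA-seq samples and the NT2 MethylC-seq sample were not used here.

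The submitters' processing notes name BWA 0.6.1, TopHat2 2.0.5 and Bismark 0.7.7 without saying which was used for which assay, and list hg19 and mm9 among the genome builds. The largest positions on each chromosome fit within hg19 for the human and mm9 for the mouse lists. No chromosome lengths were used: each chromosome was taken to end at the largest position in any list of the species, both for covered shares and for shifts. The peak caller, its threshold, the filters and any control library are not given in the sources used here. As deposited by the authors, the lists hold start and end positions in base pairs with no height, fold or p-value. The NT2 DRIPc-seq list gives a strand for each peak, and the 3T3 DRIPc-seq list is split by strand under 2 track lines, per the file headers. The E14 and 3T3 DRIP-seq lists carry 4 class names and a score that is 0 in every row, which was not used. Because the authors' threshold decides what is listed, a peak missing from a list is a region not called there, and lists from libraries of different depth can differ in length for that reason as well.

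For each comparison, the share of peaks of the first list touched by at least 1 bp of the second was computed with strand ignored, with an exact Clopper-Pearson 95% interval from scipy 1.17.1. The same share was taken after 100 circular shifts of the second list within chromosomes, with a fixed seed, and after 100 shifts of 20 to 200 kb that keep the regional density of peaks. The second kind of shift was added after the data were examined. These shares describe the lists, and no p-value was computed, since there is 1 list per group. Shared counts were checked with bedtools 2.31.1, which gave the same number in all 7 comparisons. Peaks were also split into quartiles of length. Covered length was compared with digest A in bins of 10 Mb, as a log2 ratio with 20 kb added to both lengths and the median of all bins subtracted. Peak edges were compared among touching peaks, counting start and end positions within 50 bp of a like edge of the other list, beside 20 shifts of 1 to 5 kb. For peaks of like length, the length ratio was held between 0.8 and 1.25 and the peak had to touch exactly 1 peak of the other list. Other software was Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

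The comparisons, their tests, the alternative settings and the rule for named regions were fixed before the data were examined. The rule took gene names where an annotation of the build was at hand; otherwise it took the 5 longest regions of each list and, for each comparison and direction, the 5 longest regions of a list with no overlap in the other, after peaks within 1 bp were merged. No annotation of hg19 or mm9 was used here, so the gene lists, the position of peaks relative to genes and the share of DRIPc-seq peaks on the strand of the gene were not analysed, and human and mouse regions were not compared with each other. Alternatives required at least 50% of a peak to be covered, used the longest 50% of each list, counted base pairs, merged peaks within 1 kb, or took digest B in place of digest A. Shares of K562 peaks were also computed without the 963 peaks on sequences that the digest A list does not hold, a choice made after the data were examined. The functions were tested on simulated lists: a planted share of 60% of 5000 peaks was recovered as 60%, the expected chance share of 20% for 2000 peaks was estimated as 20.04%, and 30.4% of edges planted within 50 bp were recovered as 30.4%.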

Results

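RNA:DNA hybrids, the RNA and DNA strands that pair in R-loops, were mapped in 2 human and 2 mouse cell lines. NT2 is a human embryonal carcinoma line with pluripotent properties, and K562 is a human leukaemia line of erythroid and myeloid character. E14 is a mouse embryonic stem cell line, and 3T3 is a mouse fibroblast line. In DRIP-seq, genomic DNA is cut with restriction enzymes, hybrids are recovered with an antibody and the DNA is sequenced without strand. In DRIPc-seq, the RNA strand of the recovered hybrids is sequenced, so each peak has a strand. The 9 peak lists used here comprised NT2 DRIP-seq after either of 2 enzyme mixes (digest A and digest B), NT2 DRIP-seq with RNase A, NT2 DRIP-seq with RNase H, NT2 DRIPc-seq, K562 DRIP-seq, E14 DRIP-seq, 3T3 DRIP-seq and 3T3 DRIPc-seq. Digest A used HindIII, EcoRI, BsrGI, XbaI and SspI, and the labels name it for every list except digest B, which was made with BamHI, NcoI, ApaLI, NheI and PvuII.

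Each list came from 1 sample, except that of NT2 DRIPc-seq, which stood for 2 samples, so no comparison below has a replicate check. The lists give positions without read counts, and the depth of each library is therefore unknown. Intervals are exact Clopper-Pearson 95% intervals for a share of peaks; they cover counting error only, and peaks are not independent replicates. Human positions are on hg19 and mouse positions on mm9, counted from 1, and regions are given without gene names because no annotation of either build was used.

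NT2 DRIP peaks covered a small and uneven part of the genome. The digest A list held 67126 peaks with a median length of 1206 bp, covering 135.7 Mb, or 4.39% of the chromosomes, each taken up to the last peak of any human list. Digest B gave 49331 peaks that were longer, with a median of 2841 bp, and covered 194.8 Mb. Chromosome 19 had the highest cover in both, 20.8% in digest A and 21.8% in digest B, followed by chromosomes 17 and 22. Chromosomes 13 and 18 had the lowest cover among the autosomes, 0.922% and 1.10% in digest A. K562 showed the same chromosome at the top, with 22.3% of chromosome 19 covered by its list of 51445 peaks.

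**Figure D1:**
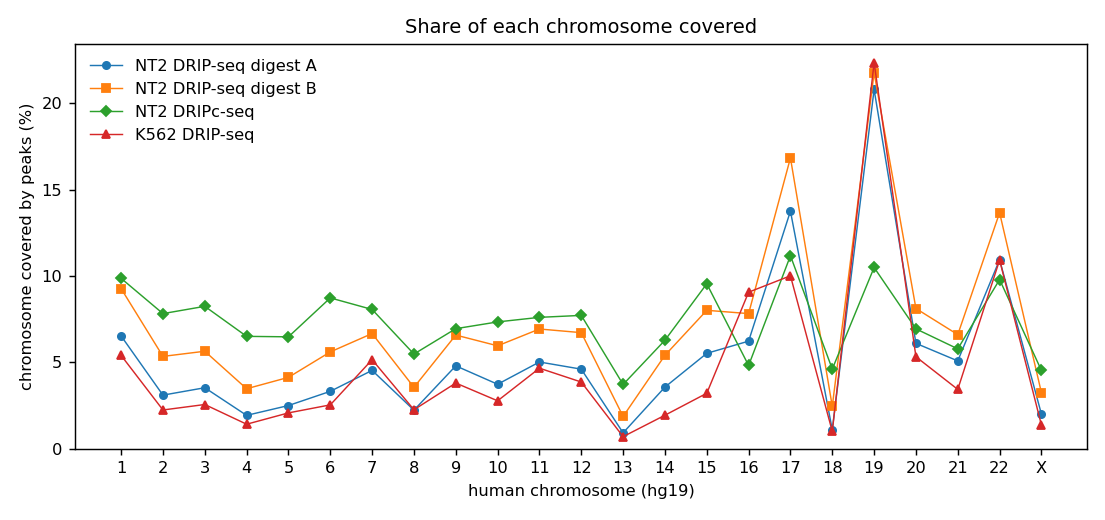
The vertical axis gives the percentage of each human chromosome (horizontal axis, hg19) covered by peaks in the NT2 digest A, NT2 digest B, NT2 DRIPc-seq and K562 lists, 1 point per chromosome and list; lines only join the points of a list. Chromosome 19 reaches 20.8% in digest A and 22.3% in K562, against 10.5% in NT2 DRIPc-seq.

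The first comparison set the NT2 peaks of digest A beside those of digest B. The enzymes and the library changed together, so an effect of the enzymes cannot be told apart from a difference between libraries. Most digest A peaks were also found with digest B: 51575 of 67126, or 76.8% (76.5 to 77.2%), touched a digest B peak by at least 1 bp. In the other direction, 70.9% (70.5 to 71.3%) of digest B peaks touched a digest A peak. Long peaks were shared far more often than short ones, with 51.7% of the shortest quartile of digest A peaks found in digest B and 97.2% of the longest quartile. A long peak is also more likely to be touched by chance, and shifted shares were not computed by quartile, here or below. Peaks seen with digest A alone had a median length of 543 bp, against 1567 bp for those seen with both. The longest digest A region without a digest B peak lay on chromosome 15 from 77303442 to 77313748 (10.3 kb) and was also present in the RNase A and RNase H lists. The longest digest B region without a digest A peak lay on chromosome 6 from 161033534 to 161068172 (34.6 kb) and was also present in NT2 DRIPc-seq. Random placement of digest B peaks gave a mean of 10.9% over 100 circular shifts within chromosomes, and 24.8% when the peaks were moved by only 20 to 200 kb.

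The RNase A and RNase H libraries addressed the nature of the recovered material, since RNase H destroys RNA paired with DNA and serves as the negative control. After RNase A, 65.5% (65.2 to 65.9%) of digest A peaks were found, and the list held 59825 peaks covering 149.8 Mb. By chromosome this share ran from 42.9% on chromosome 6 to 89.3% on chromosome 16, while that in digest B ran from 69.2% to 80.7%. Digest A is a separate library, so an effect of RNase A cannot be told apart from a difference between libraries. After RNase H, only 8998 peaks covering 15.38 Mb were listed, and 5.09% (4.93 to 5.26%) of digest A peaks were found. The same limit holds for this share. Of digest A peaks, 34.1% were in neither the RNase A nor the RNase H list. A further 60.8% were in the RNase A list but not in the RNase H list. Set against the RNase A list in place of digest A, 8.66% (8.44 to 8.89%) of 59825 peaks were found after RNase H. The share found after RNase A rose from 38.6% in the shortest quartile of digest A peaks to 91.1% in the longest. After RNase H it was between 2.99% and 4.21% in the 3 shorter quartiles and 10.04% in the longest. On chromosome Y, however, 147 of 208 digest A peaks (70.7%) were found after RNase H, and chromosome 21 was next with 11.7%. Shifts within chromosomes gave 10.2% for RNase A and 1.37% for RNase H, and shifts of 20 to 200 kb gave 23.1% and 2.93%. When at least 50% of a digest A peak had to be covered, the share found after RNase H was 3.01%. Shifted shares, here and below, were computed only for a touch of at least 1 bp, so none stands beside this value.

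The RNase H list overlapped the RNase A list more than it did digest A. Of the 8998 RNase H peaks, 64.5% (63.5 to 65.5%) touched an RNase A peak and 38.2% (37.2 to 39.2%) a digest A peak, against 24.1% and 20.1% with shifts of 20 to 200 kb. The other 5558 touched no digest A peak, and 32.2% touched none of the digest A, digest B and RNase A peaks. Those in none of these lists had a median length of 488 bp. The longest RNase H regions lay on chromosome 4 from 49090817 to 49158720 (67.9 kb), on chromosome 21 from 10772524 to 10840181 (67.7 kb) and on chromosome 16 from 46385751 to 46445867 (60.1 kb). All 3 were also present in every other human list, and whether the signal there came from hybrids was not tested. The longest digest A region lacking an RNase H peak, on chromosome 9 from 139711196 to 139765690 (54.5 kb), was present in the digest B, RNase A, DRIPc-seq and K562 lists.

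Some long digest A regions had no peak in the RNase A list either. The longest was on chromosome 17 from 46646148 to 46676264 (30.1 kb), and it was present in digest B, DRIPc-seq and K562. Others lay on chromosome 1 from 3599456 to 3622140 (22.7 kb) and on chromosome 6 from 30545220 to 30560733 (15.5 kb). The RNase A list held 20059 regions with no digest A peak, the longest on chromosome 16 from 3042328 to 3068374 (26.0 kb), which was shared with the RNase H and K562 lists. Relative to digest A, the RNase A list covered more of the first 40 Mb of chromosome 12, with a median log2 ratio of 1.26 over 4 bins of 10 Mb after the median of all bins was subtracted. It covered less of chromosome 6 after 90 Mb, with a median log2 ratio of -1.03 over 9 bins, where K562 had a median of -0.59, about as far from 0 as the SD of its other bins (0.57). The SD of the ratio over the remaining bins was 0.52 and 0.51, respectively. Chromosome 16 was higher in the RNase A list, with a median log2 ratio of 0.96 over 10 bins (SD of other bins 0.52), and in K562 the median over digest A was 0.83 (SD of other bins 0.55). These blocks were chosen after the ratios of all bins had been seen.

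**Figure D2:**
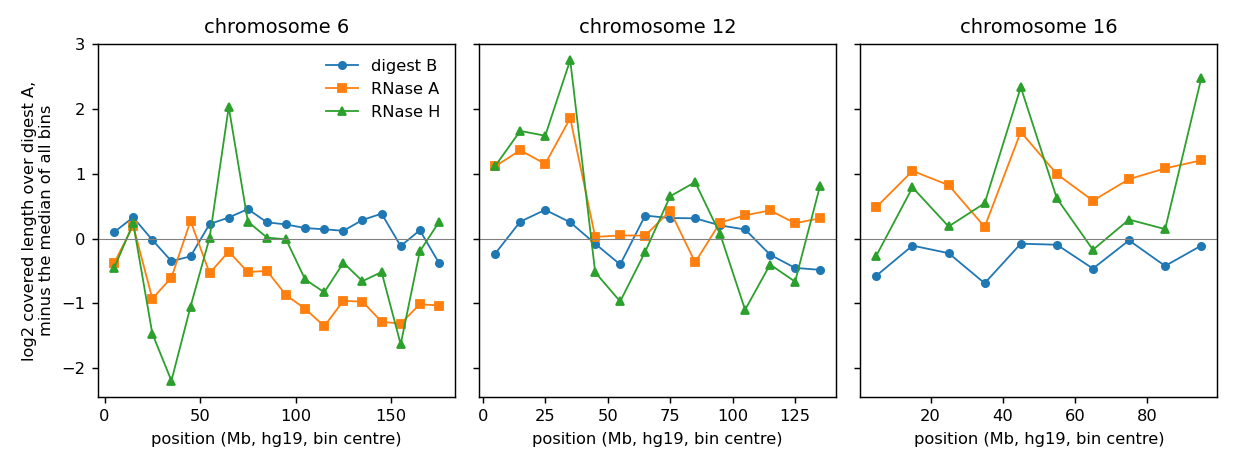
The vertical axis gives the log2 ratio of the length covered by the NT2 digest B, RNase A or RNase H list to that covered by digest A, in bins of 10 Mb along chromosomes 6, 12 and 16 (horizontal axis, Mb on hg19), minus the median of all bins. Each point is 1 bin; RNase A lies between 1.12 and 1.86 in the first 4 bins of chromosome 12 and at or below 0.44 in the rest of that chromosome.

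K562 and NT2 were compared with the same enzymes to see which peaks were shared between the lists of the cell lines. A difference between cell types cannot be told apart here from one between libraries. Of the NT2 digest A peaks, 36747 of 67126, or 54.7% (54.4 to 55.1%), touched a K562 peak, and 46.5% had at least 50% of their length covered. The share touching a K562 peak was 50.4% (49.99 to 50.9%) for digest B peaks and 32.0% (31.7 to 32.3%) for NT2 DRIPc peaks. Of the 51445 K562 peaks, 67.3% (66.9 to 67.7%) touched a digest A peak, and 26.0% (25.6 to 26.3%) touched neither a digest A nor a digest B peak. Of all K562 peaks, 963 lay on sequences with no peak in the digest A list; without them the shares were 68.6% (68.2 to 69.02%) and 24.5% (24.2 to 24.9%). NT2 peaks seen with both digests were found in K562 in 61.8% of cases, against 31.5% for those seen with digest A alone. These groups also differed in length, with medians of 1567 and 543 bp, which was not adjusted for. A core of 20272 digest A peaks, 30.2% of the list, was present in digest B, RNase A, NT2 DRIPc-seq and K562, with a median length of 2614 bp. The share of digest A peaks found in K562 rose from 29.3% in the shortest quartile to 79.9% in the longest. For digest A peaks touching a K562 peak, placement by chance gave 8.21% with shifts within chromosomes and 19.6% with shifts of 20 to 200 kb.

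Among regions present in NT2 and without a K562 peak, the longest was on chromosome 9 from 115821870 to 115849482 (27.6 kb), followed by chromosome 9 from 136300316 to 136327087 (26.8 kb) and chromosome 5 from 1031091 to 1055173 (24.1 kb). Each of these 3 was present in all of the other NT2 lists, RNase H included, and whether the signal there came from hybrids was not tested. In K562, the longest regions without a digest A peak were on unplaced sequences that no NT2 list contains. On the assembled chromosomes, the longest was on chromosome 1 from 202133354 to 202165154 (31.8 kb), which was also present in the NT2 RNase A and RNase H lists. The next, on chromosome 16 from 89034593 to 89061046 (26.4 kb), was present in the same NT2 lists. The nature of the signal at both was likewise not tested. Digest A peaks at 28 to 34 Mb of chromosome 6 were found in K562 in 35.2% of cases (30.1 to 40.4%, 347 peaks), against 48.8% on the rest of the chromosome. The RNase A list of NT2 also held fewer of them, 31.1% (26.3 to 36.3%) against 44.2%, so a lower share was not seen in K562 alone. Whether both lists were low there for the same reason was not tested. This window was chosen after the data were seen.

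**Figure D3:**
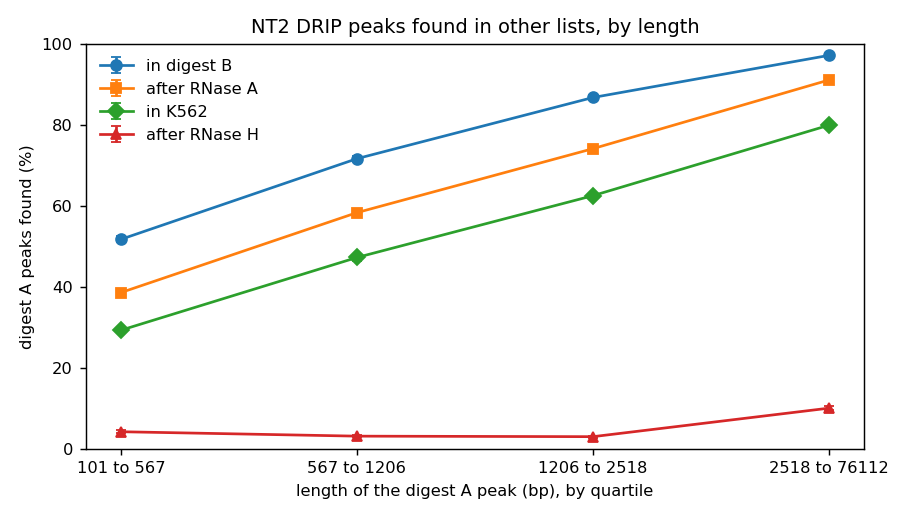
The vertical axis gives the percentage of NT2 digest A peaks found in the digest B, RNase A, K562 and RNase H lists, and the horizontal axis the quartile of peak length in bp; bars are exact 95% intervals for counting error. From the shortest to the longest quartile the share rises from 51.7% to 97.2% for digest B and from 29.3% to 79.9% for K562, and it is at most 10.04% for RNase H. Shares expected by chance were not computed by quartile.

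DRIPc-seq in NT2 placed hybrids on a strand, and its list covered more of the genome than any NT2 DRIP-seq list. The list held 88310 peaks, 46159 on the plus and 42151 on the minus strand, covering 223.6 Mb with a median length of 1749 bp. It stands for 2 samples and depth is unknown, so the larger cover cannot be read as a difference between assays. In 3T3 the DRIPc-seq list covered less than the DRIP-seq list, 86.55 against 122.7 Mb. Of the length covered by NT2 DRIPc-seq, 96.0% carried 1 strand only. Plus strand peaks touched a minus strand peak in 9.28% of cases, against a mean of 7.19% (at most 7.95%) with shifts of 20 to 200 kb. DRIPc-seq cover was spread more evenly over chromosomes than DRIP cover, with 11.2% on chromosome 17, 10.5% on chromosome 19 and 3.72% on chromosome 13. Of the DRIPc peaks, 45.6% (45.3 to 45.9%) touched a digest A peak, and 39.2% (38.8 to 39.5%) touched no peak of digest A, digest B or RNase A. When at least 50% of the DRIPc peak had to be covered, the share found in digest A was 29.8%. For the 45.6% that touched a digest A peak, shifts within chromosomes gave 8.91% and shifts of 20 to 200 kb gave 16.3%. Shifted shares were not computed for 50% cover.

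Seen from the DRIP side, 61.4% (61.0 to 61.8%) of digest A peaks touched a DRIPc peak. A plus strand peak alone was found at 28.5% of digest A peaks, a minus strand peak alone at 26.3% and both strands at 6.68%. Digest A peaks with both strands were longer, with a median of 3435 bp against 759 bp for those with neither. The longest DRIPc regions without a digest A peak were on the minus strand, on chromosome 2 from 218706583 to 218754679 (48.1 kb) and on chromosome 4 from 115936519 to 115984582 (48.1 kb). The region on chromosome 2 was also present in the digest B and RNase A lists, and that on chromosome 4 in no other human list. The longest digest A region without DRIPc signal, on chromosome 14 from 105941229 to 105972035 (30.8 kb), was present in every other DRIP list from human cells. Of the RNase H peaks, 19.2% (18.4 to 20.03%) touched a DRIPc peak, against 15.8% with shifts of 20 to 200 kb.

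In the mouse lines, embryonic stem cells and fibroblasts were compared with the same enzymes. The E14 list held 53859 peaks covering 129.8 Mb, and the 3T3 list held 35894 peaks covering 122.7 Mb. Of the E14 peaks, 47.8% (47.4 to 48.2%) touched a 3T3 peak, and 61.6% (61.1 to 62.1%) of 3T3 peaks touched an E14 peak. Chromosome 11 had the highest cover in both, 8.16% in E14 and 8.70% in 3T3. The longest E14 region, on chromosome 12 from 22162241 to 22462114 (299.9 kb), had no 3T3 DRIP peak but touched a 3T3 DRIPc peak. The longest 3T3 regions without an E14 peak lay on chromosome 11 from 67322074 to 67408165 (86.1 kb) and on chromosome 10 from 58505016 to 58553382 (48.4 kb), both also present in 3T3 DRIPc-seq. For E14 peaks in 3T3, placement by chance gave 7.41% with shifts within chromosomes and 16.1% with shifts of 20 to 200 kb. For 3T3 peaks in E14, the same shifts gave 9.82% and 20.95%.

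The mouse DRIP lists also carry a class name for each peak, which is the authors' own. Of peaks named Noisy_BroadPeak, 70.9% (70.0 to 71.7%) of the 10393 in E14 were found in 3T3 and 84.9% (83.7 to 86.0%) of the 3950 in 3T3 were found in E14. Peaks named Sparse_SharpPeak differed between the directions, with 29.4% (27.1 to 31.7%) of those in E14 found in 3T3 and 82.1% (78.5 to 85.4%) of those in 3T3 found in E14, an interval that overlaps that of Noisy_BroadPeak. Peaks of this class had a median length of 396 bp in E14 and 2381 bp in 3T3, so the difference in share cannot be told apart from one in length. Peaks named Noisy_MedPeak made up 74.0% of the E14 list, and 44.3% (43.8 to 44.8%) of them were found in 3T3. Those in 3T3 were found in E14 in 58.8% of cases (58.3 to 59.4%). Peaks named Sparse_MedPeak in E14 were found in 3T3 in 13.4% of cases (11.9 to 14.9%), and those in 3T3 were found in E14 in 46.0% (43.2 to 48.9%), the lowest share of the 4 classes in both directions.

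In 3T3 fibroblasts, the DRIPc-seq list held 39905 peaks, 20233 on the plus and 19672 on the minus strand, covering 86.55 Mb. Of these peaks, 58.2% (57.8 to 58.7%) touched a 3T3 DRIP peak, and 45.6% (45.1 to 46.1%) of 3T3 DRIP peaks touched a DRIPc peak. At 3T3 DRIP peaks, a plus strand peak alone was found in 18.3% of cases, a minus strand peak alone in 17.7% and both strands in 9.67%. The longest DRIPc regions without a 3T3 DRIP peak were on the minus strand, on chromosome 1 from 176763831 to 176823930 (60.1 kb) and on chromosome 11 from 47051501 to 47109030 (57.5 kb). For DRIPc peaks touching a 3T3 DRIP peak, shifts within chromosomes gave 7.31% and shifts of 20 to 200 kb gave 16.7%. The name of this list mentions RNase A and its track lines carry the letters RA, while the labels name no RNase treatment, so whether this library was treated with RNase A is not known.

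**Figure D4:**
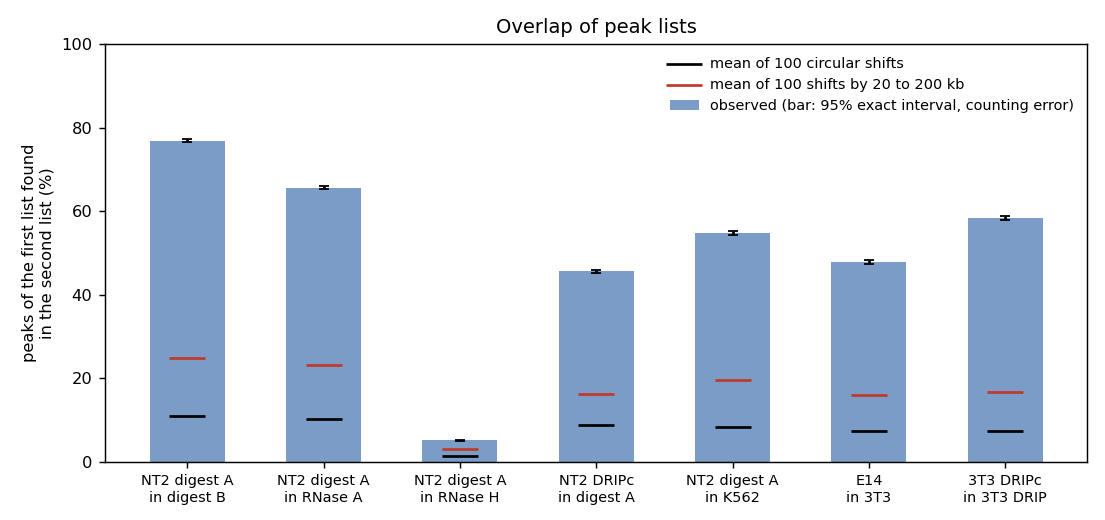
Bars give the percentage of peaks of the first list that touch a peak of the second by at least 1 bp (vertical axis) for the 7 comparisons (horizontal axis), with exact 95% intervals for counting error; black and red marks give the mean of 100 circular shifts and of 100 shifts by 20 to 200 kb. The share is highest for digest A in digest B, 76.8%, and lowest for digest A in RNase H, 5.09%, where the red mark stands at 2.93%.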

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

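Tests of whether peak length alone moved the edges, and of the second window with an alternate haplotype, were written before their results were seen; the other 7 tests in this part were chosen after the result was seen.

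The K562 list holds 536 peaks on 9 alternate haplotype sequences, 511 of them on the 7 haplotypes of chromosome 6, and 426 peaks on 36 unplaced or unlocalized sequences. No NT2 list contains such sequences, so these peaks counted as not found in the shares of K562 peaks found in NT2; without them and 1 mitochondrial peak, 68.6% of K562 peaks touched a digest A peak, against 67.3% of all. In the mouse DRIP-seq lists, 305 rows of E14 and 99 rows of 3T3 carry a minus sign, although the assay is unstranded and all other rows of these lists carry a plus sign.

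Digest A peaks at 28 to 34 Mb of chromosome 6, the region of these haplotypes, were found in K562 in 35.2% of cases, against 48.8% on the rest of the chromosome. A difference of K562 cells alone is argued against by the RNase A list of NT2, which held 31.1% of the same peaks (26.3 to 36.3%), against 44.2% on the rest of the chromosome. Peaks peculiar to the digest A list are argued against by digest B, which held 86.5% (82.4 to 89.9%). At 43 to 45 Mb of chromosome 17, which also has an alternate haplotype, K562 held 33.7% of digest A peaks (27.3 to 40.5%), against 55.7% on the rest of that chromosome, but the RNase A list, which holds no haplotype peak, also fell there, to 45.5% (38.6 to 52.5%) against 68.6%. Reads drawn to alternate haplotypes may therefore be involved or not, and cannot be told apart from another deficit that the K562 and RNase A lists have in common; a K562 difference beside a separate one in the RNase A library was not tested.

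Among touching peaks of the DRIP-seq lists, 13.4% of digest A edges lay within 50 bp of an edge in K562, cut with the same enzymes (2.42% when shifted), and 2.74% within 50 bp of a digest B edge (1.66% when shifted), a ratio of 4.89; for E14 against 3T3, also cut with the same enzymes, the share was lower, 6.50% (1.68% when shifted). With the RNA sequenced the same enzymes gave lower shares, 3.72% for digest A against NT2 DRIPc-seq (2.60% when shifted) and 3.11% for 3T3 DRIP-seq against 3T3 DRIPc-seq (2.54% when shifted). A shared cell line as the source of common edges would put the share against digest B at or above that against K562. The share against K562 was instead higher by 10.7 percentage points. These are the values in which the pattern was seen, so they are not separate evidence. The greater length of digest B peaks as the whole cause is argued against, since the ratio was 4.72 among peaks of like length. Restriction fragments may therefore set part of the edges in DRIP-seq, where the DNA is sequenced; the peak caller's settings for each list remain open, and no biological explanation was tested.

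The RNase A list covered more of the first 40 Mb of chromosome 12 than digest A, with a median log2 ratio of 1.26 over the 4 bins. In the rest of the chromosome the median was 0.24 and no bin reached the lowest of the 4. This cannot decide on a deeper RNase A library, because subtracting the median of all bins removes a gain common to them. The 4 bins were also chosen for standing out. A loss in digest A alone is argued against by digest B, whose median there was 0.26 over digest A. The RNase H list was also raised there, with a median of 1.62 against an SD of 1.12 over other bins. A copy number difference left in the lists of the RNase libraries may therefore be involved. This is weak, since 52 of 318 other bins reached the lowest of the 4. Bins without a peak in any list stood at 2.397, a value set by the added 20 kb and the subtracted median. They are among the 52 and in the SD, so neither measures RNase H signal alone. An effect of the RNase A treatment itself remains open and untested.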

How the results depend on the processing

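The settings that leave out 2 regions or use DRIPc peaks of 1 strand were chosen after seeing the data. Of 41 alternative values, 9 stayed within the counting interval of the reported share and 32 did not. The interval is narrow, and the cause of each move was not tested. In every planned setting that gives all 4 shares, digest A peaks were found most often in digest B, then after RNase A, in K562 and after RNase H; with digest B as the NT2 list the last 3 kept that order.

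With at least 50% of a peak covered, digest A shares were 68.2% in digest B, 58.0% after RNase A, 3.01% after RNase H and 46.5% in K562, and the others were 29.8% for NT2 DRIPc in digest A, 39.8% for E14 in 3T3 and 48.8% for 3T3 DRIPc in 3T3 DRIP. With the longest 50% of each list, digest A shares were 77.3%, 64.8%, 4.82% and 58.2% in the same order, with 44.3% for NT2 DRIPc and 56.1% for 3T3 DRIPc. Counting base pairs gave 77.5%, 70.1%, 4.81% and 59.3%, with 31.1% for NT2 DRIPc and 41.5% for 3T3 DRIPc. Merging peaks within 1 kb gave 73.2%, 62.6%, 5.59% and 51.0%, with 43.3% for NT2 DRIPc, 44.7% for E14 and 55.3% for 3T3 DRIPc. With digest B in place of digest A, the share was 60.2% after RNase A, 4.82% after RNase H and 50.4% in K562, and 54.5% of NT2 DRIPc peaks were found in digest B. NT2 DRIPc peaks of the plus strand were found in digest A in 45.2% of cases and those of the minus strand in 46.0%. Without 28 to 34 Mb of chromosome 6 and the first 40 Mb of chromosome 12, all 5 NT2 shares stayed within their intervals.

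No paired analysis was possible because each group has 1 peak list, and the list of NT2 DRIPc-seq does not separate its 2 samples. The alternatives for the strand share within genes, for peak location and for gene lists were not run, since no annotation of the builds was used. Depth is unknown, so a peak missing from a list may be a peak below the threshold of a shallower library, and requiring 50% cover lowered the RNase H share to 3.01% without separating these cases.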

Other observations

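The measurements in this part were chosen after the data were seen. In NT2 cells, neighbouring DRIPc peaks of opposite strands that did not overlap and lay within 2 kb of each other were more often divergent (minus strand peak on the left) than convergent, 1197 of 1977 pairs or 60.5% (58.4 to 62.7%). In 3T3 fibroblasts, 772 of 1545 such pairs, or 49.97% (47.4 to 52.5%), were divergent. Among overlapping pairs the divergent share was 46.7% (45.3 to 48.1%) in NT2 and 52.5% (50.9 to 54.0%) in 3T3. Plus strand peaks touched a minus strand peak in 9.28% of cases in NT2, against 7.19% with shifts of 20 to 200 kb, and in 19.7% of cases in 3T3, against 4.33%. The difference between the lines was not tested, and whether the 3T3 library was treated with RNase A is not known.

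Some NT2 DRIP peaks without a K562 peak followed one another. On chromosome 15 from 99195486 to 99933278, 63 consecutive digest A peaks that were also found in digest B had no K562 peak. A run of 50 such peaks lay on chromosome 17 from 71304249 to 72199231, and a run of 40 on chromosome 4 from 18612634 to 20635376. In the RNase A list the longest run was 38 peaks, on chromosome 4 from 20267712 to 20635376. In 1000 shuffles of the found or missing status within chromosomes, the longest run was 29 peaks for K562 (median of the longest 13) and 21 for RNase A (median 11). The shuffles treat neighbouring peaks as exchangeable, so they do not separate these runs from the regional clustering of peaks. The chromosome 4 runs share their last position, so this region held no peak of the K562 list or of the RNase A list of NT2.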
